A study of Ciona robusta with 7 samples.

How the data were processed

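Single cells of the Mesp lineage were purified by cell sorting from stage 38 juveniles of *Ciona robusta* and made into SMART-seq2 libraries on 7 plates, per the labels. The deposited table holds raw counts of reads per gene and barcode, whole numbers in every cell, and featureCounts is the only tool that the labels name. Its version is not given in the sources used here, and neither are the aligner, its settings, the trimming and the strand setting. No molecular identifiers were counted, so intervals and floors cover counting error only. Each barcode column carries its plate, and 96 columns per plate gave 672 barcodes, which is more than the 386 cells of the design text. Near-empty barcodes were therefore removed by the number of genes, and barcodes with at least 1000 genes above 0 were kept.

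Row names are gene models of the KH2013 set. The table pairs 11061 of 15231 genes with orthologue-style names and leaves 4170 with an ID only, and these names were used as given. None of the IDs matched an entry of the RefSeq gene table available, so no coordinates are given. Where several genes share a name, the ID stands beside it. The table also holds 5 reporter sequences, which were left out of totals, clustering and tests. NKX2-3 was taken as Nk4 and MYF5 as the single myogenic factor, a matching made after the values were seen. Each barcode sequence occurs on several plates, so shared barcodes were tested for being the same cell. Over 16 pairs of plates and 546 shared barcodes, the median correlations of same and different barcodes differed by at most 0.028, and they were treated as different cells.

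Counts were scaled to 10000 per cell and logged, 2000 variable genes and 20 principal components were taken, and cells were grouped by Leiden clustering on 15 neighbours at resolution 0.8 (scanpy 1.11.5, python-igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Genes seen in fewer than 5 kept cells were left out of clustering. Clusters were named from marker lists fixed before the values were seen. No doublet caller was run. To keep a gene from defining the cluster it was tested in, genes were split at random in 2 parts, cells were clustered on each part, and each gene was tested with classes from the part that does not hold it. Classes of the 2 parts were linked by largest overlap, and linked classes that shared most cells with the same main cluster were joined. This joining rule was added after a class of 33 cells found in both parts had been left without a name. A joined class with a Jaccard index of 0.3 or less to its main cluster was not compared.

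Reads were summed per plate and class for plates with at least 5 cells on each side. Sums were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with the plate as a block, TMM normalization, filterByExpr and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. All adjusted p values of genes in the report come from this test. Cells are not replicates. The p values measure how the difference between the 2 sides of a comparison varies between plates, which is partly technical. Several comparisons rest on 2 or 3 plates. In clusters 5 and 6 and in all pairs of clusters the prior degrees of freedom were estimated as infinite, so the spread was pooled completely over genes and very small adjusted p values there are not to be taken at face value. Log2 fold changes with their SE and plate counts are given instead. Each SE was computed from the fold change and the statistic of the same test. In those comparisons it therefore carries the same pooling over genes and is not a spread over plates. In the other fits they were 8.21, 12.3, 6.82 and 8.21 for clusters 1 to 4. Genes with 3 reads or fewer on 1 side are given as reads without a fold.

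Named genes were chosen by a rule set before the values were seen. For each comparison it took the 10 largest positive and 10 largest negative fold changes among genes that passed, had a name and changed the same way in every plate. It added up to 4 members of each fixed list with the smallest adjusted p, and a fixed set of lineage regulators. The 18 fixed lists were matched by name, and accidental matches such as MYLK or TPMT were removed after the names were seen. Lists were tested with camera (limma) with a preset correlation of 0.01 and with an estimated correlation, adjusted over lists and clusters, and for pairs over lists and pairs. Shares of cells carry exact Clopper-Pearson 95% intervals in the tables. A permutation test of shares by plate was run and dropped, since it takes cells as replicates. Correlations within plates used cells thinned to 20000 reads, 274 cells in 5 plates after 11 shallower ones were left out, with an exact sign-flip test over plates and Benjamini-Hochberg adjustment.

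The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. The changed genes were drawn only from those above a minimum mean count. The recovered percents therefore do not cover tested genes with fewer reads. The simulated changes were set to 4-fold and 32-fold after smaller ones were barely recovered. Random sets of as many cells per plate were drawn 10 times per cluster as a background for counts of genes. Alternatives tried were DESeq2 size factors, DESeq2's Wald test (DESeq2 1.42.0), no filter, no replicate block, leaving out each replicate, other resolutions, gene minimums of 500 and 2000, thinning, classes from all variable genes, 1000 variable genes with 10 components, and centring within plates. The pairs of clusters, a minimum of 3 cells, a second split of the genes, plates 4, 5 and 7 alone and lists as matched were added after the data were seen. Divisions of the sums that part every plate, for clusters 1 and 2, were added after the other divisions were seen. A comparison of clusters 4 and 1 was run and dropped. Genes shown as levels by cluster were selected after the clusters were seen. Figures were drawn with matplotlib 3.10.9. Some items that the rule names are not reported here.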

Results

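The series held single-cell RNA sequencing of *Ciona robusta*, a tunicate whose heart and pharyngeal muscles arise from a shared set of precursors that express Mesp. Cells of this lineage were purified by cell sorting from stage 38 juveniles and sequenced by SMART-seq2 in 7 plates of 96 barcodes. All 7 plates formed 1 group, so the comparisons below set classes of cells against each other within plates, with the plate as the replicate. The deposited table held 84728369 reads in 15231 genes. Plate totals were 4842962, 3703107, 19514359, 25448806, 4360044, 21093903 and 5765188 reads for plates 2 to 8. Of 672 barcodes, 315 held at least 1000 genes and were kept, and these took 98.2% of the reads. Plates 2 to 8 gave 21, 28, 85, 81, 17, 70 and 13 kept cells. A kept cell had a median of 148206 reads and 2267 genes, and plate medians were 187491, 45648, 124904, 164687, 161149, 161113 and 270548 reads. The design text states 386 cells, and 387 barcodes held at least 200 genes. Gene names are the orthologue-style names deposited in the table, and many stand for a family of paralogues. Reads of near-identical copies could have been split or lost in the authors' counting, so such members are uncertain.

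Transcripts of the ribosome led the whole population. Ribosomal protein genes took 43.1% ± 1.5 of the reads (SD, n = 7 plates) and 18 of the 20 most abundant named genes. RPS2, a small-subunit protein, stood first at 15730 ± 1434 CPM (read counts scaled by the library total, SD, n = 7). The 2 non-ribosomal genes among the 20 were MYL10/2/5/7, a regulatory myosin light chain, at 8736 ± 2428 CPM and FTMT, a ferritin, at 8244 ± 4124 CPM.

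The kept cells fell into 7 clusters, which were named from marker lists fixed beforehand. Cluster 5 (33 cells) was called heart muscle-like for its sarcomere and calcium-handling genes and a heart regulator sum of 509 ± 89.2 CPM (SD, n = 3 plates). Most of that sum was GATA4/5/6 at 406 ± 117 CPM. Clusters 4 (34 cells) and 6 (25 cells) carried sarcomere genes with regulators of pharyngeal muscle and were called pharyngeal muscle-like. Cluster 2 (77 cells) was given the fixed name non-muscle mesoderm-like for its heart regulators (656 ± 292 CPM, SD, n = 6 plates), with fewer sarcomere transcripts (11190 ± 1758 CPM) than clusters 4, 5 and 6 but more than cluster 1 (2752 ± 489.8 CPM, n = 7), so it was not free of muscle transcripts. Its matrix sum (7280 ± 4152 CPM) was not above that of cluster 6 (8376 ± 2914 CPM, n = 4). Clusters 1 (89 cells), 3 (36 cells) and 7 (21 cells) were left unnamed and kept their numbers. The fixed names include ciliated-like and neural-like, and cluster 3 carried genes of both lists, but neither name was given. Cluster 7 did not come back when cells were clustered on separate parts of the genes, so no test of it on separate genes was made. In the tests of the other clusters its cells were counted within other classes. Cluster 7 did come back with 1000 variable genes and 10 components (mean Jaccard index 0.597, 17 cells in both parts). With classes from all variable genes, which reuse the genes tested, 7 genes passed as higher and 173 as lower in 2 plates. Cluster 1 held 29.3% ± 4.16 of a plate's cells (mean and SD, n = 7), and cluster 5 9.14% ± 6.27. Cluster 2 held a mean of 23.3%, from 9.52% to 42.9% of a plate. Cluster 3 ranged from 0 of 13 cells in plate 8 (exact Clopper-Pearson upper limit 24.7%) to 29.4% in plate 6 (exact Clopper-Pearson 95% interval 10.3 to 56.0%). Each plate is 1 library, so the shares are described without a test between plates.

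**Figure D1:**
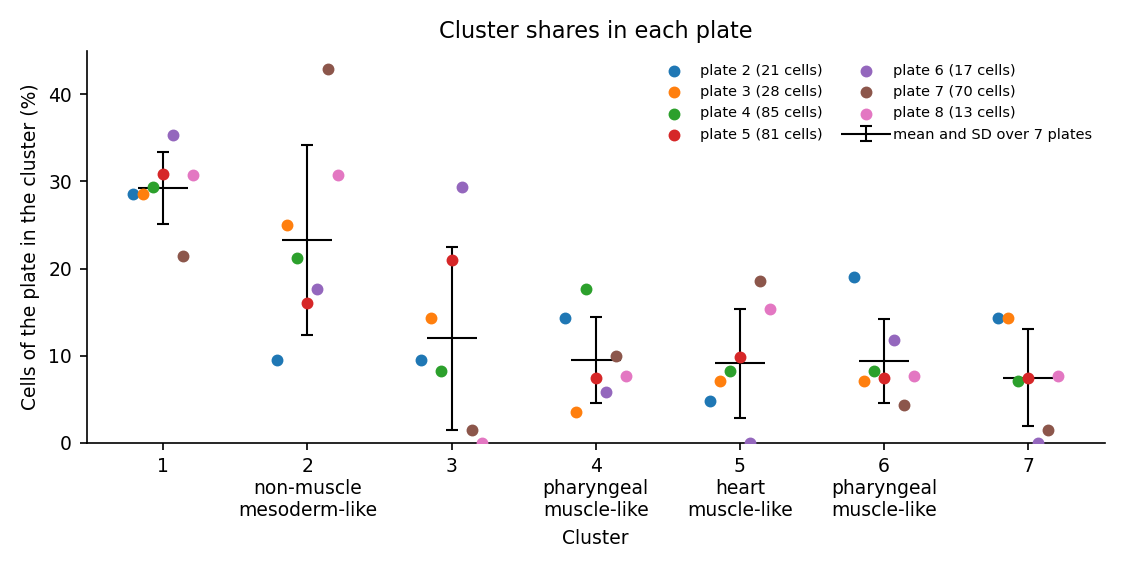
Share of each plate's kept cells in each of the 7 clusters, in percent, with 1 point per plate and bars for the mean and SD over 7 plates. Cluster 1 ran from 21.4% to 35.3% of a plate, and cluster 3 from 0 to 29.4%.

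Heart muscle-like cells were set against all other cells of the same plates to ask which transcripts mark this class. A tropomyosin, TPM1/2 (KH.C3.661), which covers actin filaments, stood at 10156 ± 3013 CPM in cluster 5 against 109 ± 142 CPM in the other cells (SD, n = 3 plates; log2 fold change 7.43 ± 0.24, SE). The muscle myosin heavy chain MYH1/2 rose from 48.2 ± 52.8 to 4348 ± 1309 CPM. Calcium release and uptake went with it: the calcium buffer CASQ1/2 rose by 5.32 ± 0.46, the release channel RYR1/2/3 by 3.59 ± 0.58, the junctional anchor JPH1/2/3 by 3.45 ± 1.04 and the calcium pump ATP2A1/2 (KH.L116.40) by 2.78 ± 0.56. Cardiac transcription factors rose as well, NKX2-3, the deposited name matched to the Nk4 regulator of heart fate, by 3.26 ± 0.64 and GATA4/5/6 by 3.14 ± 0.72. The fixed list of heart regulators names both Nk4 and GATA4/5/6, but the deposited name NKX2-3 did not match it. NKX2-3 is therefore left out of every count, median, sum, test and correlation of that list in this report. Of its 6 measured genes 1 rose and 5 did not pass, with 1 higher and 2 lower adjusted over the list alone and a median log2 fold change of -1.89. The median over all 10509 genes of this comparison was -2.12, so the list's median lay slightly above that of all genes. Camera, which sets a list against the other genes, ranked it upward and did not call it (adjusted p = 0.531). All of the genes named as higher so far changed the same way in each of the 3 plates. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 112 genes as higher and 130 as lower in cluster 5, of 10509 tested in 3 plates. DESeq2's Wald test passed 160 as higher and 1129 as lower, so the balance depends on the test.

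Part of the sarcomere list rose in cluster 5. Of 36 sarcomere genes measured, 16 rose, 2 fell and 18 did not pass. Adjusted over the list alone, 19 rose and 4 fell. The light chain MYL1/3/4/6 rose by 2.06 and the troponin I gene TNNI1/2/3 by 1.98. Camera called the sarcomere list higher (adjusted p = 1.16e-16 with a preset correlation), though not with an estimated correlation (adjusted p = 0.395). Of 12 calcium-handling genes 4 rose, none fell and 8 did not pass, with 4 higher and 1 lower adjusted over the list alone. That list was called higher at adjusted p = 7.34e-05, and adjusted p = 0.46 with an estimated correlation. Outside the contractile apparatus, the lipase LIPI rose by 7.25, the organic anion transporter SLCO2B1 by 7.64 and the vesicle fusion gene SNAP47 by 7.73. Among 80 matrix genes 5 rose, 8 fell and 67 did not pass, with 5 higher and 9 lower adjusted over the list alone. Fibulin FBLN1/2 (3.61) and ADAMTSL5 (4.28) were among those that rose, while the list's median log2 fold change was -2.47, against -2.12 over all genes. The list's median was -1.86 with genes of 0 reads on a side at their bound. Camera ranked this list upward too and did not call it (adjusted p = 0.314).

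Some regulators of pharyngeal muscle went the other way in cluster 5. EBF1/2/3/4, the COE factor that drives pharyngeal muscle fate, fell to 15.4 CPM against 350.1 CPM (log2 fold change -4.60 ± 0.87, SE, n = 3 plates). Of 7 pharyngeal muscle regulators, 2 fell, 5 did not pass and none rose, with 4 lower adjusted over the list alone. That list was called lower (adjusted p = 0.0401, or 0.567 with an estimated correlation). Other low transcripts included the replication clamp PCNA (-5.57), the secreted Wnt antagonist SFRP5 (-6.89), the cadherin CDH-4 (-6.64), the hemicentin HMCN1 (KH.C4.506) (-5.99) and the collagen COL6A1/2/3/5/6 (-2.88). The lectin MBL1/2 (KH.C5.404) changed by -2.55. Of 68 ribosomal protein genes 10 were lower and 58 did not pass, with 21 lower adjusted over the list alone and RPLP2 at -0.81 ± 0.17. Camera ranked that list upward and did not call it (adjusted p = 0.359). Its median of -0.33 lay above the -2.12 of all genes. HAND/1/2 and MMP21, further markers of the heart lineages, did not pass (log2 fold change 1.70 ± 1.95 and 0.63 ± 1.79). In simulated data of this comparison, 21% of 32-fold changes and 0 of the 4-fold changes were recovered, so most changes of these sizes were missed there. Random sets of as many cells passed at most 5 genes as higher and 16 as lower in 10 draws.

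Setting cluster 5 against clusters 4 and 6 asked how heart muscle-like and pharyngeal muscle-like cells differ. The heart side carried NKX2-3 at 520.0 ± 162 CPM against 1.94 ± 0.656 CPM (SD, n = 3 plates; log2 fold change 8.03 ± 0.92, SE) and GATA4/5/6 at 382 against 13.5 CPM (log2 fold change 6.08 ± 0.99). The pharyngeal side carried EBF1/2/3/4 at 543 CPM against 13.5 CPM in cluster 5 (log2 fold change -5.35 ± 0.93). MYF5, the deposited name for the single myogenic factor of the MyoD family, stood at 216 CPM against 6 CPM there (log2 fold change -6.18 ± 1.80, adjusted p = 0.0193). All 4 regulators went the same way in all 3 plates. ISL1/2, a LIM-homeobox factor of the pharyngeal muscle list, did not pass (-0.21 ± 0.86). The test passed 130 genes as higher and 141 as lower in cluster 5, of 7755.

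Some contractile genes differed between the 2 muscle classes. MYH1/2 stood at 3828 CPM in cluster 5 and 5.63 CPM in clusters 4 and 6 (log2 fold change 9.71 ± 0.49). The tropomyosin TPM1/2 (KH.C3.661) was higher in cluster 5 by 8.83 ± 0.37, whereas the tropomyosin TPM1/2/3/4 (KH.C14.129) was lower there by a log2 fold change of -3.09 ± 0.23. LDB3, a Z-disc protein, changed by -7.67 ± 0.69 and the sodium-calcium exchanger SLC8A1/2/3 by -3.72 ± 0.68, both lower in cluster 5. Calsequestrin CASQ1/2 was higher in cluster 5 by 4.19 ± 0.52. Of 33 sarcomere genes, 6 rose, 6 fell and 21 did not pass, and 8 rose and 8 fell adjusted over the list alone. The sarcomere list had a median log2 fold change of -0.78 and a mean of 0.06, opposite in sign, and camera did not call it (adjusted p = 0.279). The median over all genes of this comparison was -1.015. Members of this list thus parted the classes in both directions. Of 5 pharyngeal muscle regulators, 2 fell and 3 did not pass, with 4 lower adjusted over the list alone. Camera called them lower (adjusted p = 0.0123, but adjusted p = 0.728 with an estimated correlation).

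Other single genes parted the same classes. LIPI (9.50), SI:CH211-39A7.1 (10.27), CLC-2/5 (KH.C11.627) (9.62) and FBLN1/2 (2.71) were higher in cluster 5. RERGL, a Ras-like gene, had 374 reads in cluster 5 and 0 in the pharyngeal muscle-like cells. Lower in cluster 5 were the collagen COL6A1/2/3/5/6 (-4.59), the laminin LAMB1/2 (-7.32), the lectin MBL1/2 (KH.C5.404) (-5.15), the ligand WNT2/4/5 (-6.57) and PCNA (-5.53). The adhesion gene DSCAM/2/3/4 (KH.C3.390) and the synaptic matrix gene AGRN had 1981 and 822 reads in clusters 4 and 6 and 0 in cluster 5. Of 54 matrix genes, 6 rose, 5 fell and 43 did not pass, so this list did not move 1 way (9 higher and 10 lower adjusted over the list alone). Of 31 signalling genes 1 rose, 1 fell and 29 did not pass, with 1 higher and 2 lower adjusted over the list alone. Part of this comparison rests on cluster 4, for which wells with 2 cells were not excluded.

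**Figure D2:**
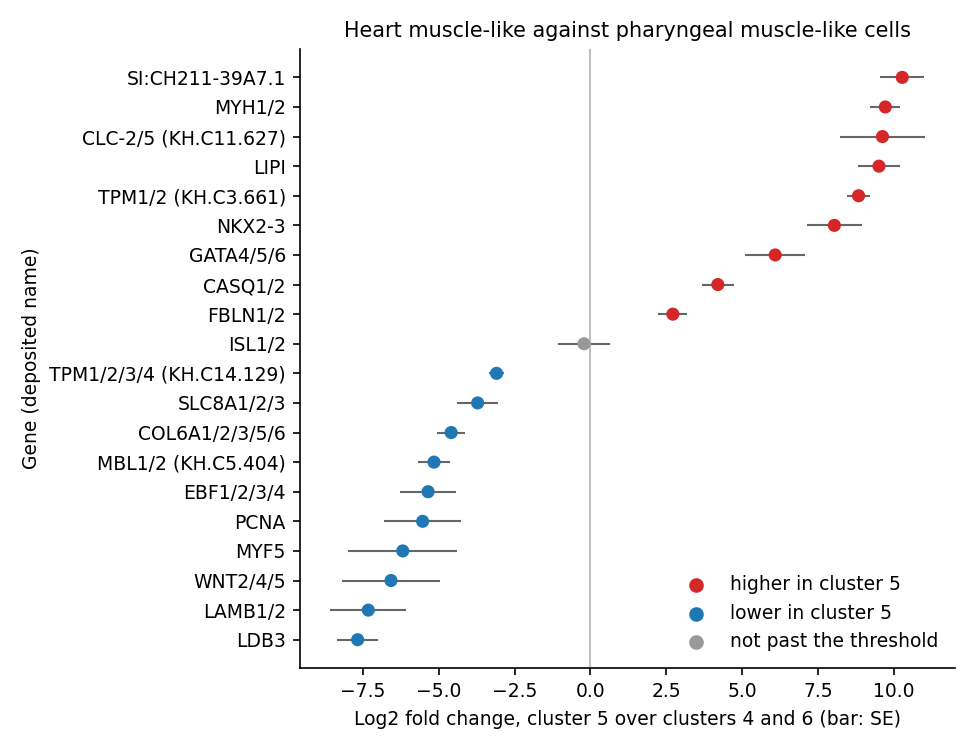
Log2 fold change of cluster 5 over clusters 4 and 6 for genes named in the text with more than 3 reads on each side, in 3 plates. Bars show the SE of the fit, in which the spread was pooled over genes, and not a spread over plates. NKX2-3 and GATA4/5/6 lie on the heart side, and EBF1/2/3/4 and MYF5 on the pharyngeal side.

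Cluster 6 was compared with the other cells to describe the pharyngeal muscle-like class with the highest muscle levels. Channel, transporter and receptor genes were among its large rises in the 2 plates tested. The L-type calcium channel CACNA1C stood at 552 CPM against 6.22 CPM (log2 fold change 6.54 ± 0.90, SE, n = 2 plates). The exchanger SLC8A1/2/3 rose by 5.42 ± 0.83, the inward rectifier KCNJ12 by 7.62 ± 1.98 and BVES, a cyclic-AMP-binding membrane protein of muscle, by 6.67 ± 0.83. The creatine transporter SLC6A8 rose by 7.04 ± 1.03, the carbonic anhydrase CA7 by 6.78 ± 0.95 and the peptide receptor NPBWR2 by 8.08 ± 0.93. The test passed 182 genes as higher and 187 as lower, of 9811. IRX1/2/3/5, a homeobox gene, had 204 reads in cluster 6 and 2 in the other cells.

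Parts of the sarcomere and calcium-handling lists rose in cluster 6. Of 35 sarcomere genes, 14 rose, 3 fell and 18 did not pass, with 20 higher and 4 lower adjusted over the list alone. The muscle actin ACTA1/2 (KH.C1.570) rose by 4.92 and LDB3 by 4.28. The tropomyosins TPM1/2 (KH.C7.260) and TPM1/2 (KH.C3.661) went the other way, at -5.27 and -5.09. Camera called the sarcomere list higher (adjusted p = 1.42e-13, and adjusted p = 0.576 with an estimated correlation). Of 14 calcium-handling genes 7 rose and 7 did not pass, the same 7 adjusted over the list alone, and this list was called higher at adjusted p = 4.30e-10 (0.569 with an estimated correlation). Small heat shock protein HSPB1 rose by 5.82, the stress factor ATF3 by 2.68, the lectin MBL1/2 (KH.C5.404) by 6.28 and fibronectin FN1 (KH.L92.15) by 4.16. HSPB1 and ATF3 belong to the fixed dissociation stress list. Of its 10 genes 2 rose, 1 fell and 7 did not pass, with 2 higher and 3 lower adjusted over the list alone. The ligands WNT2 (5.03) and WNT2/4/5 (3.90) rose as well.

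Some genes of replication were lower in cluster 6. PCNA changed by -5.07 ± 0.95, and the replication genes MCM3, RPA3 and DNA2 had 0 reads in the cluster against 2860, 3349 and 3212 outside it. Of 19 cell cycle genes, 2 fell and 17 did not pass, with 8 lower adjusted over the list alone. That list was called lower (adjusted p = 0.000974, or 0.576 with an estimated correlation). The matrix genes THBS3/4 (KH.C6.164) (-6.17) and COL9A1/2/3 (-4.86) fell, as did the Notch-responsive repressor HES1/4/5 (-3.42) and the chaperone HSP90B1 (-4.17). EBF1/2/3/4 and MYF5 did not pass here (1.21 ± 0.67 and 2.19 ± 0.86). With 2 plates the test had 1 residual degree of freedom, random sets of as many cells passed up to 52 genes as higher and 123 as lower in 10 draws, and only 29% of simulated 32-fold changes were recovered.

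Cluster 4 also carried muscle transcripts. The troponin C gene TNNC2 (KH.C12.417) stood at 166 CPM against 4.95 CPM in the other cells (log2 fold change 5.04 ± 0.55, SE, n = 3 plates). The tropomyosin TPM1/2/3/4 (KH.C14.129) rose by 2.69 ± 0.28 to 13899.5 CPM, the troponin T gene TNNT1/2/3 by 2.06 ± 0.19 and the light chain MYL1/3/4/6 by 1.47 ± 0.15. The calmodulin-like CALML6 rose by 2.71, the guidance receptor ROBO1/2 (KH.L19.1) by 2.54, the tubulin TUB1/3 (KH.C8.892) by 3.19 and the zinc finger factor ZEB1/2 by 2.57. PAR1 (3.86), the galectin LGALS4/8/9 (3.47), the small heat shock protein HSP26/27 (3.04) and COL6A1/2/3/5/6 (2.53) were higher too. Lower in cluster 4 were MYH1/2 at -5.78, TPM1/2 (KH.C3.661) at -4.75 and NKX2-3 at -5.28. The fatty acid binding gene FABP1/6 (KH.C7.153) (-5.94), the annexin ANXA13/7 (-5.78) and THBS3/4 (KH.C6.164) (-4.59) fell as well. MYF5 and EBF1/2/3/4 leaned higher in 3 of 3 plates without passing (log2 fold change 2.46 ± 0.55 at adjusted p = 0.0982, and 1.01 ± 0.29 at adjusted p = 0.241).

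Of 36 sarcomere genes in cluster 4, 4 rose, 2 fell and 30 did not pass, and 11 rose and 4 fell adjusted over the list alone. The list's median log2 fold change was 1.15, its mean -0.24, and camera called it higher (adjusted p = 9.25e-08, but 0.265 with an estimated correlation). Of 6 heart regulators none passed over all genes, and 3 fell adjusted over the list alone, with a median log2 fold change of -2.86 (camera adjusted p = 0.0444, or 0.556 with an estimated correlation). Of 7 pharyngeal muscle regulators none passed over all genes, and 2 rose adjusted over the list alone. Their median was 0.65 and their mean -0.90, and camera called them higher at adjusted p = 0.0449 (0.556 with an estimated correlation). In all, 27 genes passed as higher and 45 as lower, of 10556 in 3 plates. The class tested held 28 cells on a part of the genes and 44 on the other, with 27 in both (mean Jaccard index to cluster 4 0.742). It was thus not the same set as the 34 cells of the cluster. Random sets of as many cells passed up to 31 genes as higher and 43 as lower in 10 draws, so the number of genes alone does not set this cluster apart, and wells with 2 cells were not excluded.

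Within the pharyngeal muscle-like cells, clusters 4 and 6 were compared directly. Cluster 4 carried less of several muscle genes in both plates: TNNI1/2/3 changed by -3.09 ± 0.75, the troponin C gene TNNC1 (KH.C8.251) by -2.88 ± 0.70 and ACTA1/2 (KH.C1.570) by -2.87 ± 0.66. The channel CACNA1C (-5.47), SLC8A1/2/3 (-3.73), NPBWR2 (-7.28), CA7 (-7.33) and SLC6A8 (-6.21) fell further. Plate 7, with 3 cells of cluster 6, was outside this test. There CACNA1C went the other way, at 467.5% of its cluster 6 level, while SLC8A1/2/3 (20.8%) and NPBWR2 (6.02%) stayed lower in cluster 4. MBL1/2 (KH.C5.404) (-3.70), HSPB1 (-2.77) and ATF3 (-2.97) were lower too. Cluster 4 carried more PCNA, at 214 ± 17.2 against 6.65 ± 1.05 CPM (SD, n = 2 plates), and more HES1/4/5 (3.25). The actin bundler FSCN1/2 (6.09), LASP/1 (5.96), the actin-binding TAGLN/2/3 (KH.C4.230) (5.70), TPM1/2 (KH.C7.260) (5.24) and the lysyl oxidase LOXL2/3/4 (3.81) rose. The 2 lineage regulators EBF1/2/3/4 (-0.20 ± 0.70) and MYF5 (0.24 ± 0.84) did not differ detectably. Of 28 sarcomere genes 6 fell, 1 rose and 21 did not pass, with 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.24e-08, or 0.728 with an estimated correlation). Of 11 calcium-handling genes 2 fell and 9 did not pass, with 7 lower adjusted over the list alone (camera adjusted p = 4.88e-08, or 0.728 with an estimated correlation). In total 59 genes passed as higher and 84 as lower, of 5751. With cells thinned to 20000 reads these were 26 and 98, of 1429, and under DESeq2's Wald test 200 and 194. The balance thus depends on the processing. A mixture of 2 cells in the wells of cluster 4 would also lower muscle genes against cluster 6.

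**Figure D3:**
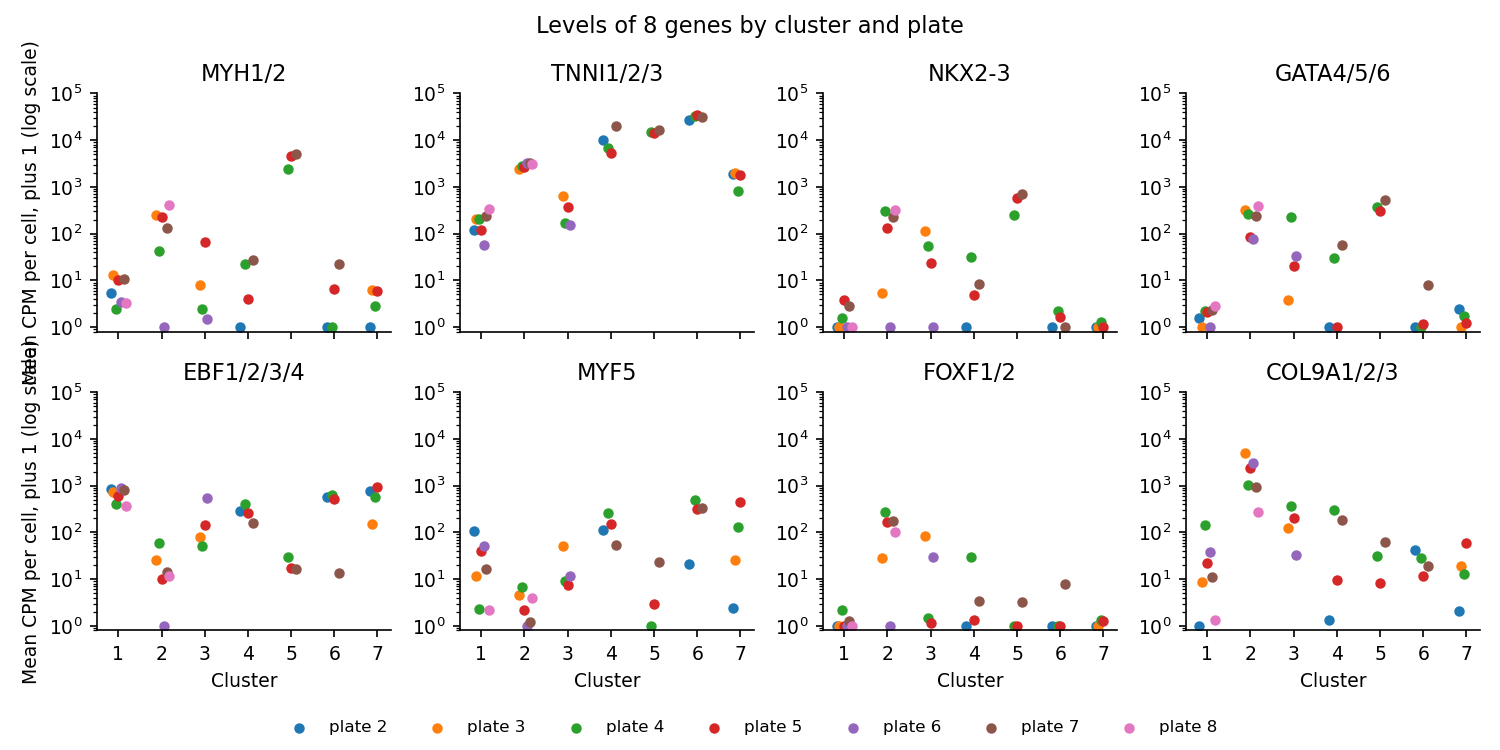
Mean CPM per cell, plus 1, on a log axis for 8 genes by cluster, with 1 point per plate that held at least 3 cells of the cluster. Means over plates were highest in cluster 5 for MYH1/2 (4014 CPM) and NKX2-3 (509.9 CPM), in cluster 1 for EBF1/2/3/4 (662 CPM) and in cluster 2 for COL9A1/2/3 (2083 CPM).

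Cluster 2 was set against the other cells to describe a class with heart regulators and fewer sarcomere transcripts than the muscle-like clusters. The homeobox gene MSX1/2/3 stood at 304 ± 205 CPM against 1.56 ± 2.47 CPM (SD, n = 4 plates; log2 fold change 8.33 ± 0.79, SE). FOXF1/2, a forkhead factor of the early heart lineage, rose by 6.14 ± 1.12, HAND/1/2 by 3.93 ± 0.91, GATA4/5/6 by 2.71 ± 0.53 and BMP2/4 (KH.C4.125) by 3.97 ± 0.75. Of 6 heart regulators 5 rose and 1 did not pass, the same 5 adjusted over the list alone, and camera called the list higher (adjusted p = 6.71e-12, or 0.109 with an estimated correlation). MMP21, a metalloproteinase that marks the first heart lineage, rose by 3.92 ± 0.92, and the second heart lineage markers DACH1/2 and MATN1/3/4 rose by 5.55 ± 1.05 and 3.68 ± 0.55. Of 13 genes in the second lineage list these 2 rose and 11 did not pass, the same 2 adjusted over the list alone, and the list's median log2 fold change was -0.51. Camera ranked the list upward, against its median and mean, and did not call it (adjusted p = 0.183). The median over all genes of this comparison was -0.44. NKX2-3 did not pass (1.03 ± 0.61). All genes named as changed moved the same way in 4 of 4 plates, and 155 genes passed as higher and 231 as lower, of 10541. A minimum of 3 cells, chosen after the data were seen, gave 80 and 242 in 6 plates. Random sets of as many cells passed at most 3 as higher and 12 as lower.

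Matrix genes changed in both directions in cluster 2. The thrombospondin THBS3/4 (KH.C6.164) rose by 7.54, the collagen COL9A1/2/3 by 4.81 and SVEP1 (KH.C5.620) by 6.88. The collagen COL6A1/2/3/5/6 (-5.48) and the hemicentin HMCN1 (KH.C4.506) (-5.59) fell. Of 84 matrix genes 8 rose, 8 fell and 68 did not pass, with 9 and 10 adjusted over the list alone, and camera did not call the list. Of 46 signalling genes 4 rose, 3 fell and 39 did not pass, with 5 higher and 5 lower adjusted over the list alone and a median log2 fold change of -0.22. Camera ranked that list upward and did not call it (adjusted p = 0.505). Its median lay above the -0.44 of all genes. Among single genes IGF1/2 (5.65) and BMP5/6/7 (4.76) rose, with the receptor FZD4 (3.93) and the membrane protein CSMD1/2/3 (6.84). The immediate-early factor EGR1/4, of the fixed dissociation stress list, rose by 1.51. Of 10 genes in that list 2 rose, 1 fell and 7 did not pass, with 5 higher and 2 lower adjusted over the list alone. Its median log2 fold change was 0.48 and its mean lay below 0, and camera, which ranked it upward, did not call it (adjusted p = 0.367). The summed list was highest in cluster 2 (8656 ± 806 CPM, SD, n = 6 plates), so stress from handling was not excluded. The ligand WNT2/4/5 (-7.34), the factor NFIC (-6.79), HSPB1 (-5.54) and MBL1/2 (KH.C5.404) (-5.54) fell.

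Some muscle genes and some pharyngeal regulators were lower in cluster 2 than in the other cells. The muscle actin ACTA1/2 (KH.C8.649) changed by -3.80, MYL10/2/5/7 by -3.54, TNNT1/2/3 by -3.17 and LDB3 by -6.45. Of 37 sarcomere genes 12 fell, 1 rose and 24 did not pass, with 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 8.09e-09, or 0.109 with an estimated correlation). EBF1/2/3/4 (-4.76) and MYF5 (-5.46) fell. ISL1/2, of the pharyngeal muscle list, had its highest cluster mean in cluster 2 (200.6 ± 164.9 CPM, SD, n = 6 plates). Of 6 pharyngeal muscle regulators 3 fell and 3 did not pass, with 4 lower adjusted over the list alone. That list was called lower (adjusted p = 5.26e-07, or 0.414 with an estimated correlation). The cytochrome oxidase gene COX4I1/2 fell by a log2 value of -1.69.

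Clusters 5 and 2, which both carried GATA4/5/6, were compared to ask how the heart muscle-like class and cluster 2 differ. MYL10/2/5/7 stood at 18765 CPM in cluster 5 and 1036 CPM in cluster 2 (log2 fold change 4.17 ± 0.16, SE, n = 3 plates). TPM1/2 (KH.C3.661) (5.77), MYL1/3/4/6 (2.63), TNNI1/2/3 (2.62) and the ubiquitin ligase TRIM54/55/63 of the sarcomere (6.91) rose in cluster 5. Of 29 sarcomere genes 16 rose, 1 fell and 12 did not pass, with 20 higher and 2 lower adjusted over the list alone. Camera called the list higher (adjusted p = 2.99e-29, or 0.626 with an estimated correlation). CASQ1/2 (4.50), RYR1/2/3 (3.84) and JPH1/2/3 (6.73) were among 4 of 9 calcium-handling genes that rose, and 5 did not pass (camera adjusted p = 3.86e-07, or 0.626 with an estimated correlation; 4 rose adjusted over the list alone). LIPI (7.28), SLCO2B1 (9.35), the collagen-binding SPARC (KH.C13.31) (4.67), FBLN1/2 (1568 ± 829 against 151 ± 109 CPM, SD) and HSPB1 (5.54) were higher as well. Higher in cluster 2 were FOXF1/2 (-7.85), DACH1/2 (-5.98), MATN1/3/4 (-4.52), MSX1/2/3 (-7.59), THBS3/4 (KH.C6.164) (-6.55), COL9A1/2/3 (-6.32), BMP5/6/7 (-5.83) and PCNA (-5.36).

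NKX2-3 (1.67 ± 0.59, adjusted p = 0.155), GATA4/5/6 (1.18 ± 0.61), HAND/1/2 (-0.57 ± 1.70) and MMP21 (-1.14 ± 1.55) did not pass between clusters 5 and 2. Of 6 heart regulators 3 fell and 3 did not pass, the same 3 adjusted over the list alone, with a median log2 fold change of -3.28, and camera did not call the list (adjusted p = 0.37). Of 7 second lineage genes 2 fell and 5 did not pass, the same 2 adjusted over the list alone. The test passed 92 genes as higher and 73 as lower in cluster 5, of 7762 in 3 plates. It recovered 46% of simulated 32-fold changes and 0 of the 4-fold changes.

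Cluster 1, the largest class, was compared with the other cells in all 7 plates to find what marks it without a named program. The class tested joined linked classes of 65 and 46 cells on a part of the genes and of 70 and 38 on the other. Their mean Jaccard indices to cluster 1 were 0.590 and 0.285. The joined class was larger than the 89 cells of cluster 1, and cells of cluster 7 were not set apart. Classes from all variable genes, which reuse the genes tested, gave 66 higher and 874 lower in 6 plates. ID1/2/3/4 (KH.C7.805), an inhibitor of differentiation factors, stood at 4022 ± 974 CPM against 1349.7 ± 640.3 CPM (SD, n = 7 plates; log2 fold change 1.67 ± 0.16, SE, adjusted p = 3.21e-05). The ligand TGFB2/3 rose from 157 ± 106 to 464 ± 122 CPM (SD) and ARG-1 by 1.97 ± 0.28, each in 7 of 7 plates. FGL2 (2.06), the small nucleolar RNP factor NAF1 (1.75), the centromeric histone CENPA (1.64) and the chaperone HSP90AB1 (0.56) rose as well. Summed over the list, pharyngeal muscle regulators stood at 1217 ± 236 CPM in cluster 1 (SD, n = 7 plates), against 849.8 ± 296 CPM in cluster 6 (n = 4) and 178 ± 80.1 CPM in cluster 5 (n = 3), while sarcomere transcripts summed to 2752 ± 489.8 CPM. EBF1/2/3/4 leaned higher in 6 of 7 plates (1.25 ± 0.35, adjusted p = 0.0508) without passing. Camera called the 6 pharyngeal muscle regulators measured higher (adjusted p = 0.0068, or 0.489 with an estimated correlation), with 2 higher adjusted over the list alone. None of 19 cell cycle genes passed, and their list was called higher at adjusted p = 0.000103 (0.109 with an estimated correlation). Of 68 ribosomal protein genes 2 rose over all genes and 32 adjusted over the list alone, RPL32 by 0.55, which was lost at a minimum of 2000 genes per cell.

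Most genes that passed in cluster 1 were lower there, with 530 lower and 59 higher, of 10421. Sarcomere genes fell together: 21 of 35 fell, 14 did not pass and none rose, with 28 lower adjusted over the list alone. This was the only list in any comparison called with both a preset correlation (adjusted p = 1.68e-26) and an estimated correlation (adjusted p = 0.0323). MYOM1/2/3, which crosslinks myosin, changed by -7.75 ± 0.84, MYBPC1/2/3 by -7.54 ± 1.13, TPM1/2 (KH.C3.661) by -6.88 ± 0.53, TNNI1/2/3 by -3.81 ± 0.34 and MYL1/3/4/6 by -2.67 ± 0.22. Of 12 calcium-handling genes 6 fell and 6 did not pass, among them CASQ1/2 (-6.67), RYR1/2/3 (-3.88) and SLC8A1/2/3 (-3.79), and 10 fell adjusted over the list alone (camera adjusted p = 5.49e-10, or 0.109 with an estimated correlation). Heart regulators fell too, GATA4/5/6 by a log2 value of -5.92 and FOXF1/2 by -7.43, and 5 of 7 fell while 2 did not pass (camera adjusted p = 3.20e-06, or 0.123 with an estimated correlation; 5 fell adjusted over the list alone). NKX2-3 (-7.33), HAND/1/2 (-5.73), DACH1/2 (-6.90) and MMP21 (-7.30) were low as well, lower in 5 of 7 plates for NKX2-3 and in 6 of 7 for the others, with no plate higher.

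Genes of the other classes were also low in cluster 1. They included THBS3/4 (KH.C6.164) (-6.87), COL9A1/2/3 (-4.56) and BMP5/6/7 (-5.39) of cluster 2, SYT1/2 (-4.25) and TEKT3 (-5.18) of cluster 3, and MBL1/2 (KH.C5.404) (-3.41) and HSPB1 (-4.43) of cluster 6. SYT1/2 and TEKT3 turned to higher at resolution 0.5, where cells of cluster 3 joined cluster 1. Of 83 matrix genes 15 fell, 1 rose and 67 did not pass, with 26 lower and 2 higher adjusted over the list alone. In simulated data 95% of 32-fold and 37% of 4-fold changes were recovered in this comparison. Random sets of as many cells passed none as higher and at most 7 as lower.

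Cluster 3 carried transcripts of cilia and of vesicle release in the 2 plates tested. The vesicle calcium sensor SYT1/2 stood at 459.7 CPM against 7.65 CPM (log2 fold change 5.59 ± 0.61, SE, n = 2 plates), and SYT15 and SYT7 rose by 6.68 ± 1.04 and 6.58 ± 1.25. The axonemal tektins TEKT3 and TEKT2 rose by 6.88 ± 0.84 and 4.88 ± 0.76, the radial spoke gene RSPH4A by 3.56 ± 0.58 and the axonemal dynein DNAH5 (KH.L156.1) by 3.52 ± 0.61. Of 43 cilia genes 5 rose, none fell and 38 did not pass, with 13 higher adjusted over the list alone. The list was called higher (adjusted p = 3.52e-13, or 0.569 with an estimated correlation). Of 13 neural genes 3 rose and 10 did not pass, the same 3 adjusted over the list alone (camera adjusted p = 0.001, or 0.567 with an estimated correlation). The vesicle adaptor MYRIP (7.93), the peptidase STE13 (8.11), HEG1 (KH.C1.707) (8.19) and the digestive-type peptidase CPA1/2/4/5 (KH.C8.638) (7.64) rose, though the last turned to lower at a minimum of 2000 genes per cell.

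Muscle genes were low in cluster 3. TNNI1/2/3 changed by -5.58 ± 0.35, ACTA1/2 (KH.C8.649) by -5.70 ± 0.36, MYL10/2/5/7 by -5.67 ± 0.40 and TPM1/2/3/4 (KH.C14.129) by -4.78 ± 0.39. Of 36 sarcomere genes 15 fell and 21 did not pass, with 17 lower adjusted over the list alone (camera adjusted p = 4.82e-22, or 0.435 with an estimated correlation). EBF1/2/3/4 (-2.71), MYF5 (-4.13), COL6A1/2/3/5/6 (-2.46), LAMB1/2 (-5.85), THBS3/4 (KH.C6.164) (-4.92), MBL1/2 (KH.C5.404) (-4.73), HSPB1 (-6.47) and LIPI (0.71 ± 0.465 against 92.6 ± 9.82 CPM, SD) fell. The test passed 137 genes as higher and 95 as lower, of 10367 in 2 plates. Random sets of as many cells passed up to 23 genes as higher and 83 as lower, and these values rest on few plates. With each cell thinned to 20000 reads only 28 genes passed in this comparison. Clusters 2, 4 and 5 had about as many genes tested after thinning (6035, 6072 and 6052, against 6055 in cluster 3). They still passed 324, 120 and 209 genes, so the smaller number tested does not by itself account for the fall. Cells of cluster 3 were deep, with a median of 247714 reads against 148206 in all kept cells. Cluster 4 was deeper still (304982) and passed more genes after thinning than the 72 before. A part of depth in the fall thus stays open.

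Across single cells within plates, muscle programs were related to the sarcomere list after thinning each cell to 1 depth (5 plates with at least 20 cells). The calcium-handling list rose with the sarcomere list in every plate (mean Spearman rho 0.691 ± 0.102, SD, n = 5 plates; exact sign-flip p = 0.0625, adjusted p = 0.153 over 27 relations). Heart regulators went with the sarcomere list at 0.195 ± 0.0958 and pharyngeal muscle regulators against it at -0.197 ± 0.109, each with the same sign in 5 of 5 plates. This was not particular to muscle programs, since the matrix (0.315 ± 0.126), hemocyte (0.176 ± 0.104), neural (-0.198 ± 0.206) and oxidative phosphorylation (-0.193 ± 0.0871) lists also kept their sign in 5 of 5. GATA4/5/6 gave 0.266 ± 0.142 and MYF5 0.309 ± 0.236 in 5 plates, and NKX2-3 0.277 ± 0.154 in 4 plates. The cell cycle list (-0.413 ± 0.0681) and the ribosome list (-0.466 ± 0.0926) ran against the sarcomere list in all 5 plates. With 5 plates the smallest two-sided exact p is 0.0625, so none of the 27 relations could pass.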

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

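Reads of 4 reporter sequences stood in the deposited table outside the genes that the comparisons used, and each count lay above the limit that a count of 0 allows. In kept cells GFP had 450 reads, LacZ 899, tagRFP 54 and tagBFP 7, while mCherry had 0 in 315 cells (upper limit 3 counts). None of the 285 barcodes under 200 genes held a read of any of the 5. GFP was seen in 29 of 315 kept cells, LacZ in 40, tagRFP in 5 and tagBFP in 3. A single cell of cluster 7 held 683 of the 899 LacZ reads. GFP was most frequent in cluster 6, with 10 of 25 cells (40%, exact Clopper-Pearson 95% interval 21.1 to 61.3%). The labels held here do not say which construct each plate carried, so no biological explanation was tested. A test of GFP in cluster 6 against the other cells, chosen after these counts were seen, found a higher share in each of the 4 plates that held any GFP read, by 20.9 to 85.1 percentage points. The other 3 plates held none and could not show a difference. The mean difference over all 7 plates was 31.2 ± 34.8 percentage points (SD; exact sign-flip p = 0.125, the smallest that 4 plates allow).

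Values per plate were also searched for plates far from the others, by the gap to the nearest plate over the whole range. None of 16 groups of 7 plate values exceeded Dixon's critical value, where chance alone flags about 1 in 20 groups.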

How the results depend on the processing

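Of 209 named genes that passed, 209 kept their direction and call under DESeq2 size factors, 208 without a filter and 205 under DESeq2's Wald test. Thinning kept 171 of 200 and no replicate block 95 of 201. In every setting but the missing block, leave-outs and a minimum of 2000 genes, 140 kept both. The Wald test passed more genes throughout: 1276, 1051, 690, 687, 1289 and 784 for clusters 1 to 6, 855 for cluster 5 against clusters 4 and 6, 523 for cluster 5 against cluster 2 and 394 for cluster 4 against cluster 6. It leaned to lower genes where edgeR did not, with 254 higher and 530 lower for cluster 6 and 168 and 355 for cluster 5 against cluster 2. Cluster 5 against clusters 4 and 6 gave 293 and 562. For cluster 4 it gave 140 and 547, a stronger lean than edgeR's. Cluster 4 against cluster 6 went the other way, with 200 and 194. With edgeR, cluster 4 leaned to higher genes with a second split of the genes (35 higher, 25 lower) and with classes from all variable genes (62 and 36). So it did without replicate 3 (69 and 62) and without replicate 6 (72 and 59). Resolution 0.5 gave 181 and 135 for a different, larger class. The class matched to cluster 4 there held 51 and 65 cells on the 2 parts of the genes (mean Jaccard index 0.448). No class was matched to cluster 6, so these counts are not those of cluster 4 alone. With no replicate block, 272 genes passed for cluster 1, 138 for cluster 5 and 88 for cluster 5 against cluster 2. With no replicate block edgeR passed 0 for clusters 3, 4 and 6 and 0 for cluster 4 against cluster 6, although 1153, 1192, 3606 and 832 had an unadjusted p under 0.05. Each cell thinned to 20000 reads gave 898, 28, 120 and 239 genes for clusters 1, 3, 4 and 6. Resolution 0.5 gave 243 for cluster 1 and 316 for that larger class matched to cluster 4, and classes from all variable genes 940 for cluster 1. A minimum of 500 genes gave 214 for cluster 2 and 120 for cluster 4, and a minimum of 2000 genes 97 for cluster 3 with 196 cells kept. Cluster 4 gave 113 with no filter and 120 with a minimum of 3 cells, the latter chosen after the data were seen. Leaving out 1 replicate gave 346 to 765 genes for cluster 1, 44 to 131 for cluster 4, 159 to 178 for cluster 5 and 102 to 153 for cluster 5 against cluster 2. Fewer plates leave fewer degrees of freedom, and for the other changes the cause was not tested.

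With an estimated correlation, 1 fixed list passed for cluster 1, and 0 for each of clusters 2 to 6 and 0 in all 3 pairs. Lists as matched by name passed 0 for cluster 5 against clusters 4 and 6, instead of 1. Cluster 1 held 16.2% of cells at resolution 1.2, 16.3% at a minimum of 500 genes and 36.2% at 2000, and cluster 7 15.2% at resolution 0.5. In cluster 1, SYT1/2 (4.43) and TEKT3 (5.72) reversed at resolution 0.5, where no class was matched to cluster 3 and 2 were matched to cluster 1, so cells of cluster 3 joined it. At a minimum of 2000 genes RPL32 (-0.01) reversed in cluster 1. So did 1 gene in cluster 3 versus other cells: CPA1/2/4/5 (KH.C8.638) log2 fold change was -3.93 there, and the cause was not tested. Cluster 3, cluster 6 and cluster 4 against cluster 6 had no value at resolution 0.5, and only clusters 1 and 3 had one at a minimum of 2000 genes. Comparisons with 2 plates had no leave-outs, and pseudocounts did not apply to counts.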

Other observations

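Clusters 1 and 7, with fewer muscle transcripts than clusters 4, 5 and 6, still carried regulators of pharyngeal muscle. EBF1/2/3/4 averaged 662 ± 208 CPM in cluster 1 (SD, n = 7 plates) and 606 ± 339 CPM in cluster 7 (n = 4), against 429.7 ± 282 CPM in cluster 6 (n = 4) and 19.3 ± 20.3 CPM in cluster 2 (n = 6), which is also low in muscle transcripts. MYF5 stood at 32.0 ± 37.8 CPM in cluster 1 (n = 7), 147 ± 200.3 CPM in cluster 7, 144 ± 87.9 CPM in cluster 4 (n = 4 each) and 288 ± 194 CPM in cluster 6 (n = 4). Sarcomere transcripts summed to 2752 ± 489.8 CPM in cluster 1, 15710 ± 4077 CPM in cluster 7 (n = 4) and 191100 ± 37330 CPM in cluster 6. These genes were chosen for display after the clusters were seen, and the order of clusters was not tested.

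Whether markers of the 2 heart lineages lay in different cells of cluster 2 was looked at after both had risen there, and detection was too low to tell. Among 75 cells thinned to 20000 reads, MMP21 was seen in 13, DACH1/2 in 19 and both in 2, where 3.29 would hold both by independence. Before thinning 7 cells held both. Wells with 2 cells and carry-over were not excluded, so this does not show that both markers lay in the same cell. In cluster 4, 2 of 30 thinned cells held both, where 0.267 would by independence, and 5 did before thinning. Cluster 2 parted into 44 and 33 cells at resolution 1.2. The smaller part was led by CG15828 (782 against 125 CPM), CPL-1 (762 against 283 CPM) and TCF7L1/2 (1110 against 424 CPM), a factor of the Wnt pathway. These parts were defined by the same genes, so their differences were not tested.

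Of the tests below, those of depth, of carry-over, of a partner from cluster 6 and of divisions within plates were chosen after the results were seen. No biological explanation was tested. Cluster 1 differed from the other cells mostly by genes that were lower in it. Transcripts missed in sums of few cells do not account for it, since random sets of as many cells gave at most 7 lower genes against 530. Depth does not account for all of it, since 663 genes were lower and 235 higher with each cell thinned to 1 total. Before thinning 530 were lower and 59 higher, but 10421 genes were tested then and 4861 after, so the change in balance was not put down to depth. Of the lower genes, 56.6% passed as higher in at least 1 of clusters 2 to 6, which would follow if 1 class was set against several specialised ones. Those comparisons share cells with this one, so part of that overlap is built in.

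Muscle transcripts appeared in nearly every cell of clusters with few of them, for example TNNI1/2/3 in 88 of 89 cells of cluster 1. Reads carried over between the barcodes of a plate could place them there. Heart muscle genes would then hold the same share of muscle reads as in the whole plate. They lay within 2-fold of it in 4 of 7 plates for cluster 1 and in 2 of 6 plates for cluster 3. Carry-over stays open for both clusters.

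Cluster 4 lay between cluster 6 and cluster 1 in muscle transcripts, as wells that held 2 cells would. Of 27 genes higher in cluster 4, 2 stood above every other cluster in plates 4, 5 and 7 (TNNC2 (KH.C12.417) and TUB1/3 (KH.C8.892)), so such wells could account for most of them. Among 39 genes nearly confined to cluster 6, 10.3% lay over 2-fold from the median ratio of cluster 4 to cluster 6, on the same side in 3 plates (3 under and 1 above). That ratio was 10.6%, 16.5% and 35.4% of the cluster 6 level in plates 4, 5 and 7. Median reads were highest in cluster 4 (304982), close to those of clusters 1 and 6 together (181049 and 116420), as such wells could give, but cluster 7 had 295506. A separate cell state and wells with a cell of cluster 6 and a cell of another cluster both stay possible.

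The sums were also regrouped in other ways to see how many genes a division unrelated to class would pass, and in each comparison 1 division, the real one, reached its own number. For cluster 1 the real division gave 589 genes and the highest of 100 drawn gave 350. For cluster 2 it gave 386 and the highest of 35 gave 2, with 3 not estimable. Plates pair the sums, however, and few of those divisions part every plate as the classes do. Of all 64 divisions of cluster 1 that do, the highest other gave 52 genes. The classes came from clustering the cells of all plates together, so they were matched across plates from the start. Exchanging sides would undo that match, so these divisions cannot exclude chance. Of 8 such divisions of cluster 2 the highest other gave 0 genes, and 8 are too few for a share under 0.05. In cluster 2, 155 genes were higher and 231 lower, and 10 random sets of as many cells passed at most 3 and 12. A cluster is never a random choice of cells, so these sets cannot exclude chance either. With 10 divisions a share under 0.05 cannot be reached. There the real and highest other numbers were 72 and 42 for cluster 4 and 242 and 24 for cluster 5. They were 271 and 36 for cluster 5 against clusters 4 and 6 and 165 and 54 for cluster 5 against cluster 2.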
